A study of Mus musculus with 6 samples.

How the data were processed

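Polyadenylated RNA from mouse bone marrow derived macrophages was sequenced in 6 libraries, 3 from cells given vehicle (ethanol) and 3 from cells given 100 µM stearic acid, each for 24 h. Per the labels' protocols, RNA was isolated with Trizol and a column kit and the libraries were made with a stranded Illumina TruSeq mRNA kit. The labels give a replicate number from 1 to 3 in each group. They do not say whether replicates came from separate animals or separate cultures, so p-values measure only the spread between these samples, which may be technical.

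A table per library was used. Per the file headers, the authors deposited for each gene a TPM value (transcripts per 1e+06, scaled so that each library sums to the same total) and an RPKM value (reads per kilobase of gene per 1e+06 reads). The submitters' processing notes name DRAGEN, with its version not given, and the mouse genome builds GRCm38 and mm10, which are the same assembly under different names. The gene annotation and the counting rule, including whether strand was used in counting, are not given in the sources used here. Reads of overlapping genes and of near-identical copies therefore cannot be assigned with certainty. Each table lists 36333 genes by name and NCBI gene number. Of the gene numbers, 35337 (97.3%) matched the RefSeq gene table of GRCm38.p6, which supplied coordinates, and 27 names that had turned into dates were replaced through their gene numbers where these matched. The 13 mitochondrially encoded mRNAs that had been listed as a sign of RNA quality were not analysed here, and neither were Mx1 and Mx2.

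The tables hold no counts, whereas the design fixed before the data were examined had assumed counts. Its written fallback was used: limma with an intensity-dependent prior (limma-trend) on log2(TPM + 1), over genes with a mean of at least 1 TPM across the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Treatment was the only term of the model. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. TPM is a share of the library, so a change is relative to all other transcripts. Mean ± SD values are in TPM with n = 3 libraries per group. For Il1b and Il1a, which lay below the filter, a two-sided exact permutation test over 20 assignments was used, whose smallest possible p is 0.1.

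Depth was recovered from the steps between RPKM values of genes with few reads. It came to 80.8, 75.3 and 58.1 M reads or read pairs (M, 1e+06; the sources used here do not settle which) for vehicle replicates 1 to 3 and to 64.0, 76.4 and 71.6 M for stearic acid replicates 1 to 3. Between 59.8% and 66.5% of the checked values came out as whole reads within a tolerance of 0.02. The remainder may rest on another gene length, so no counts were rebuilt. At these depths 1 TPM corresponds to 19.1 to 27.7 of these units per kilobase of transcript.

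Fixed before the data were examined were 24 gene lists with 476 distinct genes. They cover the inflammasome and IL-1 family, NF-kB, interferon and alternative activation genes, unfolded protein, integrated stress and NRF2 responses, fatty acid oxidation with PPAR targets, cholesterol synthesis, fatty acid synthesis, LXR targets and sphingolipid metabolism. The other lists cover the lysosome, lipid-associated macrophages, glycolysis, the cell cycle, macrophage identity, markers of 5 other kinds of cells, mitochondrial mRNAs, and immediate early with heat shock genes. Lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 21 lists that had at least 2 tested genes. Camera with an estimated correlation and fry were run beside it. Camera compares list members with the other tested genes, whereas fry tests the members alone.

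The genes named were chosen by a rule fixed at the same time, with 5 TPM in place of 5 CPM because the tables hold TPM. They are Il1b, Il1a, Il18, Nlrp3 and Casp1, the 6 largest rises and the 6 largest falls among called genes with a mean of at least 5 TPM and no overlap between groups, and from each list the 2 called members with the smallest p. A list whose called members went both ways gave the smallest-p member of each direction and the next of the commoner direction, and a list with 5 or fewer called members gave all of them. This named 66 genes, not all of which are printed. Members named because they make up a count of 5 or fewer, or as the exceptions of a list, were chosen after their values were seen.

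The test was checked on simulated libraries of the 11551 tested genes, 200 of them changed. It recovered 12% of 50 genes changed 1.25-fold, 58% of those changed 1.5-fold, 88% of those changed 2-fold and all 50 changed 4-fold. Of 11351 unchanged genes 11 were called, 7.86% of the 140 calls. In the data 24.7% of tested genes changed, and the simulated noise was independent and alike in both groups. These rates therefore need not hold for the real comparison. A planted list of 20 genes changed 1.5-fold was found, and 0 of 20 unchanged lists passed. The genes of these simulated lists varied independently, whereas estimated correlations in the fixed lists reached 0.87. The check therefore cannot show how often the preset correlation passes unchanged lists in these data.

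Alternatives were a pseudocount of 0.1, no filter on low values, the replicate number as a block, each of the 6 libraries left out in turn, an estimated correlation and fry for lists. Chosen after the data were seen were median-of-ratios scaling, RPKM, quantile normalization, a mean of at least 5 TPM, removal of each library's trend on transcript GC content and length, and a fit without the libraries numbered 2. The trend used transcript lengths and GC content from GENCODE vM21, which were matched for 97.5% of tested genes. Computation used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.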

Results

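Macrophages were grown from C57BL/6 mouse bone marrow in macrophage colony-stimulating factor (M-CSF, 10 ng/mL) for 7 days, replated at 250000 cells per well in 24-well plates and treated for 24 h. Stearic acid, a saturated fatty acid, was given at 100 µM to 3 samples, and an equal volume of its ethanol vehicle to the other 3. Transcript levels were measured by RNA sequencing of polyadenylated RNA. The depth recovered from the deposited values was 58.1 to 80.8 M reads or read pairs per library (M, 1e+06), and 11379 to 11639 genes reached 1 TPM in a library. The comparison asks which macrophage transcripts differ after exposure to stearic acid, in a series whose title concerns inflammasome activation and IL-1β. Across genes, libraries correlated at 0.996 to 0.998 within vehicle, at 0.988 to 0.996 within stearic acid and at 0.970 to 0.993 between the groups.

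**Figure D1:**
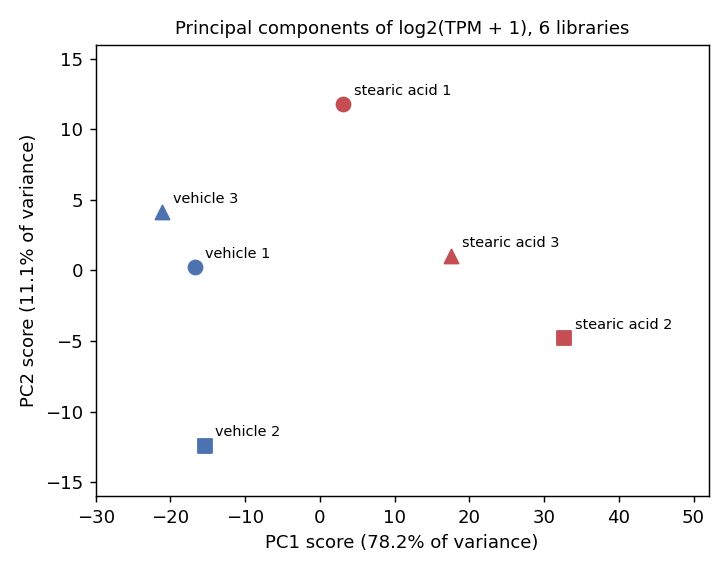
Scores of the 6 libraries on the first 2 principal components of log2(TPM + 1) over 11551 genes, with PC1 (78.2% of variance) on the x axis and PC2 (11.1%) on the y axis; blue points are vehicle and red points stearic acid, with 1 symbol per replicate number. The vehicle libraries lie between -21.1 and -15.4 on PC1 and the stearic acid libraries at 3.15, 32.7 and 17.5 for replicates 1 to 3.

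With stearic acid, many genes of glutathione and amino acid stress responses and some of lipid handling were higher, and many interferon-response and cell cycle genes and several macrophage surface genes were lower. As lists these passed in part by camera with the preset correlation, and none passed with an estimated correlation (camera adjusted p of 0.29 or more). The largest rise among the named genes was in Serpinb9b, a serine protease inhibitor (NCBI gene 20706, chromosome 13, 33027414 to 33040588, GRCm38), from 1.97 ± 0.269 to 60.7 ± 22.02 TPM (SD, n = 3 per group). Its log2 fold change was 4.32 (SE 0.22, limma adjusted p = 3.3e-05). Gsta3, a glutathione S-transferase (gene 14859, chromosome 1, 21240565 to 21265575), rose from 3.14 ± 0.203 to 44.2 ± 10.5 TPM. Procr, the endothelial protein C receptor, rose from 11.5 ± 1.29 to 93.4 ± 27.7 TPM. The next largest rises were in Slc7a11 (log2 2.57), the cystine transporter, Gdf15 (log2 2.53), a stress-induced cytokine, and Trib3 (log2 2.51), a pseudokinase induced by ATF4. These 6 rises held in each of the 6 fits that left out 1 library.

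Ms4a4a, a membrane protein, had the largest fall among the named genes. It fell from 23.1 ± 0.766 to 6.63 ± 5.97 TPM (log2 -1.94, SE 0.42, limma adjusted p = 0.015), and Adgre4, an adhesion receptor of the F4/80 family, from 8.45 ± 1.07 to 1.87 ± 1.71 TPM (log2 -1.88, SE 0.34). Fcrls, an Fc receptor-like protein, fell from 279 ± 5.41 to 103 ± 51.7 TPM. Tmem176a and Tmem176b fell by 1.61 and 1.45 on the log2 scale; these genes overlap on chromosome 6 (48841483 to 48845364 and 48833811 to 48845948), so their reads may not be separable. Hpgd, which degrades prostaglandins, fell from 162 ± 7.37 to 69.8 ± 47.2 TPM (log2 -1.44). Stearic acid replicate 1 lay nearest to vehicle in these 6 genes. None of the 6 passed without vehicle replicate 2 or without vehicle replicate 3 (limma adjusted p up to 0.074, and up to 0.12 for Hpgd, which also failed without vehicle replicate 1 or stearic acid replicate 3).

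Of 11551 genes tested, 2856 (24.7%) changed, 1482 higher and 1374 lower with stearic acid, and 189 of these changed at least 2-fold (131 higher, 58 lower). The groups did not overlap in 5147 genes (44.6% of those tested, against 10% by chance for 3 against 3). The count fell to 1073, 550 and 628 without vehicle replicate 1, 2 and 3 and to 1005 without stearic acid replicate 3, and rose to 5010 without stearic acid replicate 1. It was 1997 without stearic acid replicate 2, 1732 without the libraries numbered 2, and 1027 with no filter on low values. At least 2-fold changes numbered 122 without vehicle replicate 2, 101 without stearic acid replicate 2 and 312 without stearic acid replicate 1. Each of the 2856 changes kept its sign in every alternative in which its gene was tested. The groups did not overlap in 2839 of these genes, so leaving out libraries could not turn their sign. The filter settings and the replicate block leave folds as they are. The kept signs are therefore little evidence of stability. The stearic acid libraries differed in the size of the response: the median absolute log2 change of the called genes was 0.285, 0.601 and 0.425 in replicates 1, 2 and 3.

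**Figure D2:**
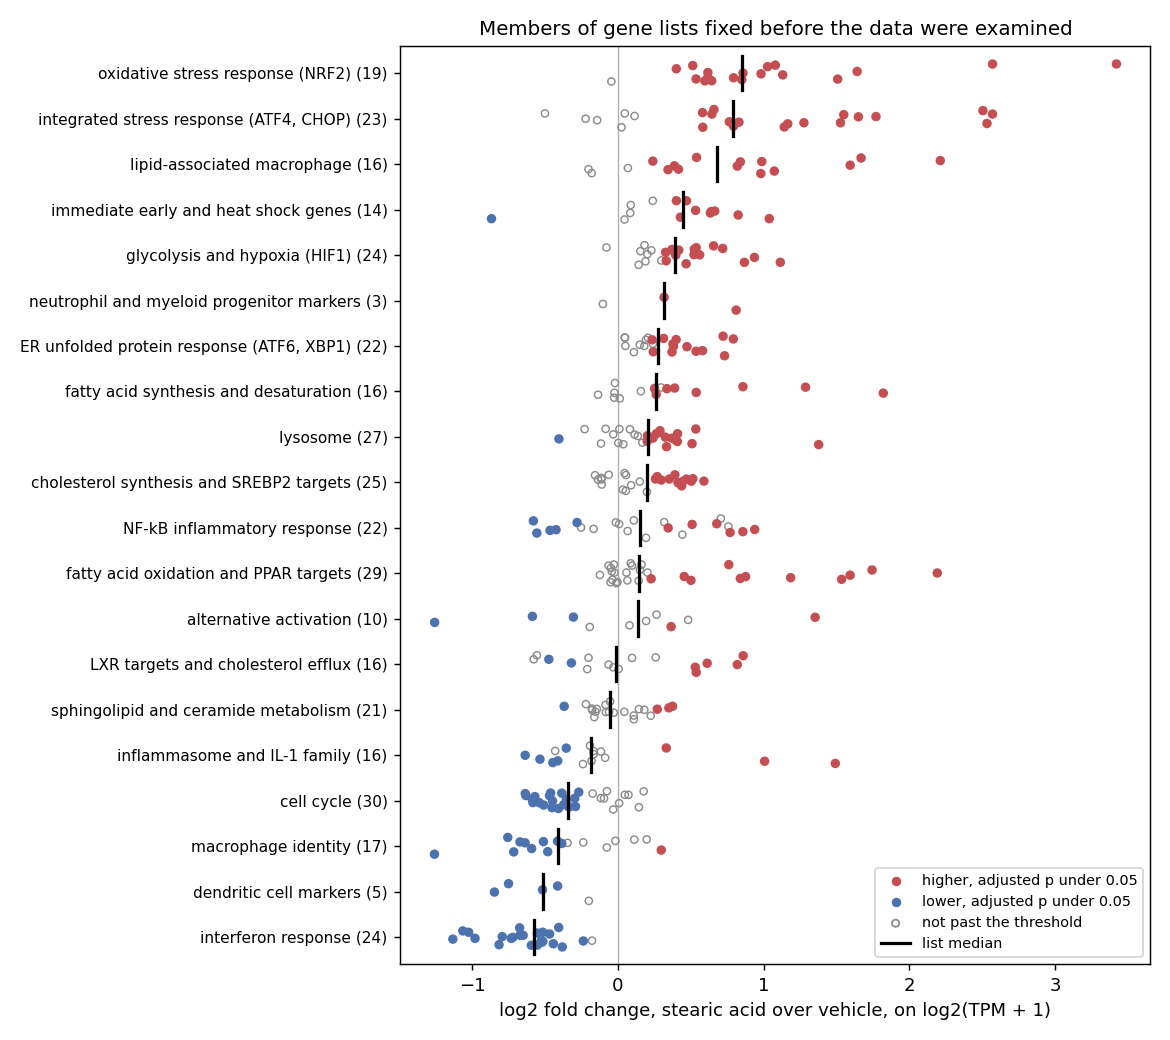
Log2 fold change of each tested member (points) of the 20 fixed gene lists with at least 3 tested members, on the x axis, with lists on the y axis and the number of tested members in parentheses; filled points passed the limma threshold of 0.05 (red higher, blue lower), open points did not, and black bars mark list medians. List medians run from -0.57 for the interferon response to 0.85 for the oxidative stress response.

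Transcripts of the IL-1 system were not raised as a group. These are mRNA levels at 24 h, and neither inflammasome activation nor IL-1β protein was measured in these libraries. Il1b (gene 16176, chromosome 2, 129364569 to 129371164), which encodes IL-1β, was low in both groups and lower with stearic acid, at 0.349 ± 0.158 TPM against 1.33 ± 0.330 TPM. It lay below the filter, and the exact permutation test gave p = 0.1, the smallest that 3 against 3 allow; the limma adjusted p was 0.034 when low values were not filtered. Il1a was at 0.138 ± 0.0252 TPM against 0.0674 ± 0.0482 TPM in vehicle (exact permutation p = 0.1; limma adjusted p = 0.17 without the filter). Il18 (gene 16173, chromosome 9, 50554700 to 50581841) fell from 13.8 ± 1.58 to 9.32 ± 1.81 TPM (log2 -0.53, SE 0.14, limma adjusted p = 0.024). Nlrp3, the inflammasome sensor (gene 216799, chromosome 11, 59541569 to 59566955), fell from 64.4 ± 5.71 to 48.1 ± 2.60 TPM (log2 -0.41, SE 0.08, limma adjusted p = 0.012). Casp1, the protease that matures IL-1β, was at 134 ± 3.26 TPM against 153 ± 8.56 TPM and did not pass (log2 -0.18, SE 0.07, limma adjusted p = 0.077; 0.071 to 0.25 over the alternatives). Il18 did not pass without vehicle replicate 2, vehicle replicate 3 or stearic acid replicate 3 (limma adjusted p up to 0.10), without the filter (0.088) or without the libraries numbered 2 (0.063), and Nlrp3 did not without vehicle replicate 1 or 3 (up to 0.064).

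In the inflammasome and IL-1 list, 3 of 16 tested genes rose, 5 fell and 8 did not pass (3 and 8 adjusted over the list alone). The risers were Il1rn, the IL-1 receptor antagonist, from 14.6 ± 2.48 to 43.7 ± 12.5 TPM (log2 1.49, SE 0.19, limma adjusted p = 0.0023), Panx1, an ATP release channel (log2 1.01), and Il18bp, a soluble inhibitor of IL-18 (log2 0.33). The fallers were Nlrp3, Txnip (log2 -0.45), Il18, Nlrp1b (log2 -0.64) and Aim2 (log2 -0.35). The list median was -0.19 and its test did not pass (camera adjusted p = 0.072); it passed as lower without the filter (0.035), with median-of-ratios scaling (0.032), RPKM (0.033) and quantile normalization (0.047). The 5 falls became 1 without vehicle replicate 1, vehicle replicate 2 or stearic acid replicate 3, 0 without vehicle replicate 3 and 9 without stearic acid replicate 1. Txnip did not pass in 4 of the 6 fits that left out 1 library, those without a vehicle library or stearic acid replicate 3 (limma adjusted p up to 0.095).

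NF-kB targets moved in both directions. Of 22 tested, 6 rose and 5 fell, with the same counts adjusted over the list alone, a median of 0.15 and a camera adjusted p of 0.34. Acod1, which makes itaconate, rose from 19.6 ± 0.195 to 39.0 ± 8.55 TPM (log2 0.94, SE 0.13, limma adjusted p = 0.0033). Tnfaip3, a negative regulator of NF-kB, rose by log2 0.51 and did not pass without vehicle replicate 2 (limma adjusted p = 0.057). The other risers were the chemokines Ccl3 (log2 0.77) and Cxcl2 (log2 0.68), the cyclooxygenase Ptgs2 (log2 0.86) and Tnfaip2 (log2 0.35). The fallers were Cd40, a costimulatory receptor (log2 -0.58), Nfkbiz (log2 -0.56), Tlr2 (log2 -0.42), Il10 (log2 -0.47) and Nfkb1 (log2 -0.28). Without vehicle replicates 1, 2 and 3 the rises numbered 3, 1 and 2 and the falls 3, 3 and 2; without stearic acid replicate 1 there were 11 rises, and without stearic acid replicate 3 there were 3 falls.

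**Figure D3:**
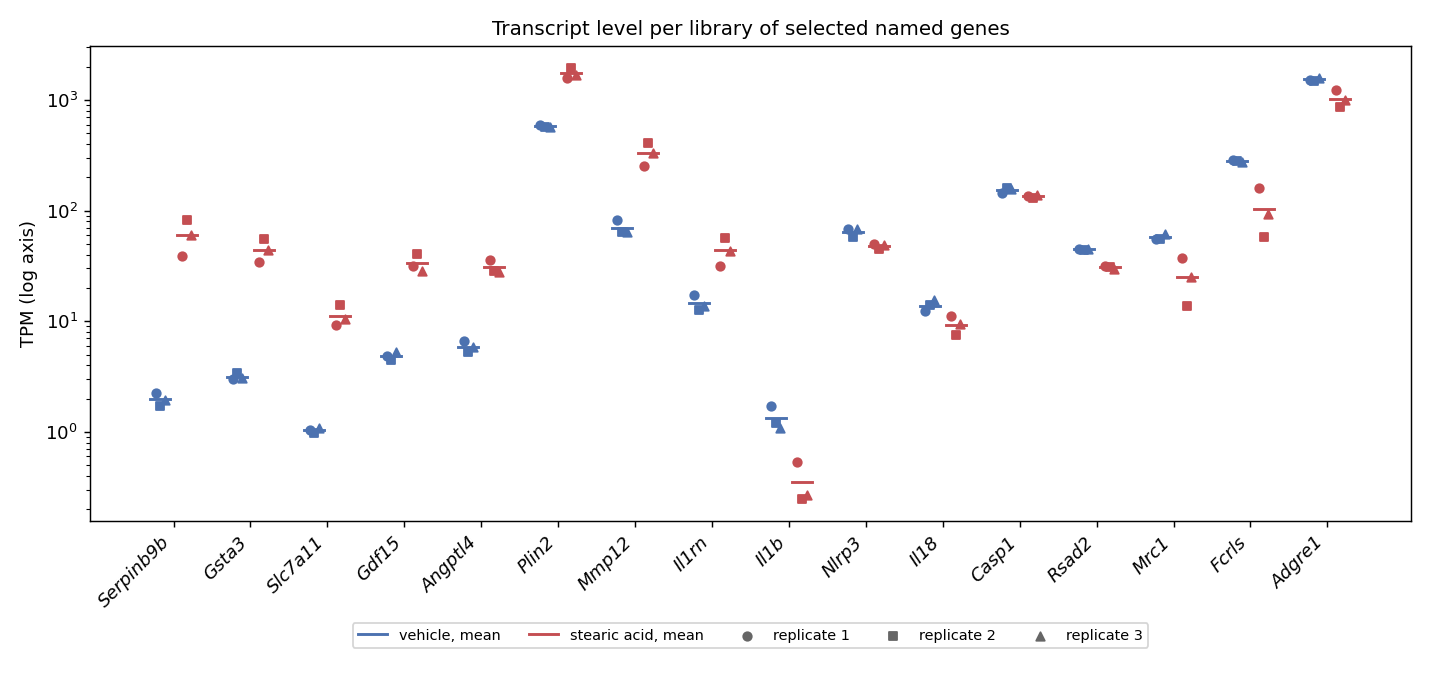
TPM per library (y axis, log scale) of 16 named genes (x axis), with vehicle in blue and stearic acid in red, 1 point per library with a symbol per replicate number, and a bar at each group mean. Plin2 has group means of 576 and 1749 TPM, Il1rn of 14.6 and 43.7 TPM, and Nlrp3 of 64.4 and 48.1 TPM for vehicle and stearic acid.

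Interferon-response genes fell together. Of 24 tested, 23 fell, also adjusted over the list alone, and the exception was Bst2 (log2 -0.18, limma adjusted p = 0.15). The median was -0.57 (camera adjusted p = 3.4e-13; adjusted p = 0.29 with an estimated correlation). Cmpk2 fell from 36.8 ± 0.926 to 24.0 ± 0.857 TPM (log2 -0.59, SE 0.07, limma adjusted p = 0.0014), and its neighbour on chromosome 12, Rsad2, which encodes the antiviral protein viperin, fell from 44.6 ± 0.477 to 30.8 ± 0.767 TPM (log2 -0.52, SE 0.06). Without vehicle replicate 2 the falls numbered 8, and without vehicle replicate 3 they numbered 10, while the list median was -0.56 and -0.58. Genes of alternative activation went both ways, with 2 of 10 higher and 3 lower (4 and 3 adjusted over the list alone), a median of 0.14 and a camera adjusted p of 0.39. Egr2 rose from 1.13 ± 0.310 to 4.45 ± 0.866 TPM (log2 1.35) and Klf4 rose by log2 0.37. Mrc1, the mannose receptor CD206, fell from 57.2 ± 3.22 to 25.2 ± 11.7 TPM (log2 -1.26, SE 0.28, limma adjusted p = 0.016), as did the scavenger receptor Cd163 (log2 -0.59) and Il4ra (log2 -0.30). The falls numbered 1, 1 and 0 without vehicle replicates 1, 2 and 3 and 1 without stearic acid replicate 3; Mrc1 did not pass without vehicle replicate 2 or 3 (limma adjusted p up to 0.076). There was 1 rise in each fit that left out a library other than stearic acid replicate 1, as Klf4 then did not pass (limma adjusted p up to 0.10).

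Genes of macrophage identity mostly fell: 10 of 17 fell, 1 rose and 6 did not pass (11 and 2 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 0.0019; adjusted p = 0.36 with an estimated correlation). Cx3cr1, the fractalkine receptor, fell from 573 ± 25.2 to 363 ± 61.6 TPM (log2 -0.67, SE 0.12, limma adjusted p = 0.0073). Adgre1, which encodes F4/80, fell from 1537 ± 40.6 to 1030 ± 186 TPM (log2 -0.59, SE 0.12, limma adjusted p = 0.011). The riser was Cd68, an endosomal glycoprotein, from 1999 ± 26.5 to 2459 ± 127 TPM (log2 0.30, SE 0.06, limma adjusted p = 0.015). The 10 falls became 6, 0 and 1 without vehicle replicates 1, 2 and 3, and 2 without the filter. Cx3cr1 did not pass without vehicle replicate 2 (limma adjusted p = 0.050), Adgre1 without vehicle replicate 2 or 3 (up to 0.061), or Cd68 without any 1 vehicle library or stearic acid replicate 3 (up to 0.075).

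Few markers of other cells reached the filter. Of 14 neutrophil and myeloid progenitor markers 3 were tested: S100a8 rose from 3.33 ± 1.19 to 6.41 ± 0.467 TPM (log2 0.81, limma adjusted p = 0.016), Mmp8 rose from 2.22 ± 0.117 to 3.01 ± 0.0552 TPM (log2 0.32), and Cebpe did not pass (camera adjusted p = 0.18). Neither rise passed without vehicle replicate 2 (limma adjusted p = 0.069 for S100a8), and Mmp8 passed only in the fit without stearic acid replicate 1 among those that left out 1 library. Of 5 tested dendritic cell markers 4 fell, the MHC class II genes H2-Eb1 (log2 -0.75), H2-Aa (log2 -0.52) and H2-Ab1 (log2 -0.41) and their transactivator Ciita (log2 -0.85), all of which macrophages also express (camera adjusted p = 0.0054; adjusted p = 0.35 with an estimated correlation). The 4 falls became 0 without any 1 vehicle library and 1 without stearic acid replicate 3. The single tested lymphoid marker, Cd79b, fell from 2.49 ± 0.206 to 1.27 ± 0.160 TPM. Of 2 tested stromal markers, Fn1 fell from 2.11 ± 0.712 to 1.03 ± 0.219 TPM and Acta2 did not pass (camera adjusted p = 0.38); the fall of Fn1 did not pass without any 1 vehicle library or stearic acid replicate 3 (limma adjusted p up to 0.098). No erythroid or mast cell marker reached the filter.

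Stress-response genes rose. Of 19 tested NRF2 targets, which handle oxidants and glutathione, 18 rose, also adjusted over the list alone, and G6pdx did not pass (log2 -0.04). Their median was 0.85 (camera adjusted p = 4.7e-15; adjusted p = 0.29 with an estimated correlation). Gsta3 and Slc7a11 led the list, the latter with a rise from 1.03 ± 0.0612 to 11.2 ± 2.53 TPM (log2 2.57, SE 0.14, limma adjusted p = 3.4e-05). Between 15 and 18 rose in each fit that left out 1 library. Of 23 tested integrated stress response genes, downstream of ATF4 and CHOP, 17 rose (17, and 1 fall, adjusted over the list alone) and 6 did not pass, with a median of 0.79 (camera adjusted p = 4.7e-10; adjusted p = 0.29 with an estimated correlation). Slc7a11 is in this list too, and Gdf15 rose from 4.87 ± 0.448 to 33.3 ± 6.29 TPM (SE of log2 0.13, limma adjusted p = 3.3e-05). The rises numbered 10 without vehicle replicate 2 and 10 without vehicle replicate 3.

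Of 22 tested genes of the endoplasmic reticulum unfolded protein response (ATF6 and XBP1), 13 rose (17 adjusted over the list alone) and 9 did not pass, with a median of 0.28 (camera adjusted p = 3.1e-08; adjusted p = 0.29 with an estimated correlation). Dnajb9 rose from 42.7 ± 1.90 to 71.7 ± 7.27 TPM (log2 0.73, SE 0.09, limma adjusted p = 0.0016) and Hyou1 from 90.1 ± 2.81 to 159 ± 28.6 TPM (log2 0.79, SE 0.12). The rises numbered 5 without any 1 vehicle library and 5 without stearic acid replicate 3. Immediate early and heat shock genes had been listed as a sign of RNA quality, which their rise does not set apart from treatment. Of 14 tested, 9 rose (10 adjusted over the list alone) and 1 fell, with a median of 0.45 (camera adjusted p = 2.3e-05; adjusted p = 0.29 with an estimated correlation). The inducible HSP70 genes Hspa1b (log2 0.83) and Hspa1a (log2 1.04) rose from 1.76 ± 0.110 to 3.89 ± 0.294 TPM and from 1.09 ± 0.193 to 3.32 ± 0.620 TPM, and are near-identical copies whose reads may be shared. Btg2, an antiproliferative gene, fell from 38.01 ± 5.18 to 21.6 ± 9.73 TPM (log2 -0.87, limma adjusted p = 0.041), which did not pass without any 1 vehicle library or stearic acid replicate 3 (limma adjusted p up to 0.15). The 9 rises became 3 without vehicle replicate 2 and 4 without vehicle replicate 3.

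Lipid-handling genes rose in part. Of 29 tested fatty acid oxidation genes and PPAR targets, 11 rose, also adjusted over the list alone, and 18 did not pass, with a median of 0.14 (camera adjusted p = 8.6e-06; adjusted p = 0.29 with an estimated correlation). Angptl4, a secreted inhibitor of lipoprotein lipase, rose from 5.90 ± 0.679 to 30.6 ± 4.33 TPM (log2 2.19, SE 0.11, limma adjusted p = 3.3e-05). Plin2, the lipid droplet coat protein (gene 11520, chromosome 4, 86626910 to 86670217), rose from 576 ± 11.7 to 1749 ± 196 TPM (log2 1.59, SE 0.08, limma adjusted p = 3.3e-05). Between 9 and 11 rose in each fit that left out 1 library. Of 16 tested genes of fatty acid synthesis and desaturation, 8 rose (10 adjusted over the list alone) and 8 did not pass, with a median of 0.26 (camera adjusted p = 6e-05; adjusted p = 0.29 with an estimated correlation). Scd2, a desaturase that acts on stearoyl-CoA, rose from 14.1 ± 0.222 to 52.7 ± 7.25 TPM (log2 1.82, SE 0.10, limma adjusted p = 3.9e-05), and Acss2, an acetyl-CoA synthetase, from 3.11 ± 0.498 to 9.01 ± 1.10 TPM (log2 1.29). The 8 rises became 5, 4 and 4 without vehicle replicates 1, 2 and 3 and 4 without stearic acid replicate 3.

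Of 25 tested cholesterol synthesis genes and SREBP2 targets, 12 rose (13 adjusted over the list alone) and 13 did not pass, with a median of 0.20 (camera adjusted p = 0.00072; adjusted p = 0.29 with an estimated correlation). Mvd, an enzyme of the mevalonate pathway, rose from 22.7 ± 0.328 to 32.7 ± 2.62 TPM (log2 0.50, SE 0.08, limma adjusted p = 0.0046). The rises numbered 3 without any 1 vehicle library and 3 without stearic acid replicate 3. Of 16 tested LXR targets, 5 rose and 2 fell (6 and 3 adjusted over the list alone). Lpcat3, which remodels phospholipids (log2 0.53), Lpl, the lipoprotein lipase, from 802 ± 46.6 to 1425 ± 193 TPM (log2 0.82), Srebf1 (log2 0.54), Mylip (log2 0.61) and the sterol transporter Abcg1 (log2 0.86) rose, and Cd5l (log2 -0.32) and Tnfaip8l1 (log2 -0.47) fell. The LXR median was -0.01 while the mean was 0.08 and the test pointed upward without passing (camera adjusted p = 0.18); it passed without stearic acid replicate 2 (0.033), and the 2 falls became 0 in each fit that left out a library other than stearic acid replicate 1, where there were 7. The median was 0.03 with median-of-ratios scaling or RPKM. Sphingolipid genes showed no shared direction, with 3 of 21 higher, 1 lower and 17 not past the threshold, the same adjusted over the list alone (median -0.05, mean 0.005, camera adjusted p = 0.84). Sgms1 (log2 0.35), Cers2 (log2 0.38) and Degs1 (log2 0.27) rose and Cers4 fell (log2 -0.37). The 3 sphingolipid rises became 0 without vehicle replicate 1, vehicle replicate 2 or stearic acid replicate 3 and 1 without vehicle replicate 3. Among the fits that left out 1 library, the fall of Cers4 passed only in that without stearic acid replicate 1.

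Genes that mark lipid-associated macrophages rose, with 13 of 16 higher (13, and 1 fall, adjusted over the list alone) and a median of 0.68 (camera adjusted p = 1.5e-09; adjusted p = 0.29 with an estimated correlation). Mmp12, macrophage elastase, rose from 70.0 ± 10.7 to 332 ± 78.2 TPM (log2 2.21, SE 0.17, limma adjusted p = 0.00023), and Plin2 and Lpl are members as well; Trem2 (log2 0.07), Apoe (log2 -0.20) and Tyrobp (log2 -0.18) did not pass. Between 10 and 13 rose in each fit that left out 1 library. Of 27 lysosomal genes, 15 rose, 1 fell and 11 did not pass (16 and 2 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 5.1e-05; adjusted p = 0.29 with an estimated correlation). The autophagy receptor Sqstm1 rose from 634 ± 38.9 to 1671 ± 352 TPM (log2 1.38, SE 0.13, limma adjusted p = 0.0006) and the protease Ctsz from 993 ± 54.0 to 1440 ± 111 TPM (log2 0.53). The 15 rises became 9, 7 and 5 without vehicle replicates 1, 2 and 3 and 7 without stearic acid replicate 3.

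Of 24 tested glycolysis and hypoxia genes, 16 rose (19 adjusted over the list alone) and 8 did not pass, with a median of 0.39 (camera adjusted p = 8.6e-09; adjusted p = 0.31 with an estimated correlation). Vegfa, an angiogenic growth factor, rose from 20.9 ± 2.24 to 38.8 ± 2.46 TPM (log2 0.87, SE 0.09, limma adjusted p = 0.001), and Egln3, an oxygen-sensing prolyl hydroxylase, from 2.02 ± 0.0524 to 5.68 ± 1.69 TPM (log2 1.11). The 16 rises became 9, 2 and 3 without vehicle replicates 1, 2 and 3, 8 without stearic acid replicate 3 and 4 without the filter. Of 30 cell cycle genes, 20 fell (21 adjusted over the list alone) and 10 did not pass, with a median of -0.35 (camera adjusted p = 1.3e-06; adjusted p = 0.30 with an estimated correlation). The mitotic kinases Cdk1 and Aurka fell from 182 ± 7.73 to 132 ± 8.97 TPM (log2 -0.46, SE 0.07, limma adjusted p = 0.0051) and from 97.2 ± 3.46 to 73.0 ± 3.26 TPM (log2 -0.41). The 20 falls became 10, 4 and 6 without vehicle replicates 1, 2 and 3, 10 without stearic acid replicate 3 and 6 without the filter. Across the 21 tested lists, 14 passed by camera, and those 14 passed in each of the 6 fits that left out 1 library. Each such fit shares all but 1 library with the full fit, so the repeated passes are little evidence of stability. With an estimated correlation 0 passed by camera, where 2 were under an unadjusted p of 0.05, and 13 passed by fry.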

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

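The planned edgeR, DESeq2 and limma-voom settings were not run because the tables hold no counts. Chosen after the data were seen were the settings with median-of-ratios scaling, RPKM, quantile normalization, at least 5 TPM, GC and length trends removed, and the libraries numbered 2 left out. Of the 2856 changed genes, all kept their sign in every setting that tested them. For the 2839 without overlap between groups, this was fixed in advance wherever libraries were left out. With no filter on low values 21632 genes were tested and 1027 changed (672 higher, 355 lower). Both the adjustment and the intensity-dependent prior then rested on more genes, and their parts in the loss of calls were not separated. Called members then fell from 23 to 11 in the interferon list, from 13 to 6 in the unfolded protein list, from 12 to 4 in the cholesterol list, from 15 to 6 in the lysosome list, from 17 to 11 in the integrated stress list, from 8 to 5 in fatty acid synthesis and from 9 to 4 in the immediate early list. NF-kB rises went from 6 to 2 and falls from 5 to 3, inflammasome falls from 5 to 2, dendritic falls from 4 to 0, alternative activation falls from 3 to 0 and neutrophil rises from 2 to 0. The 2 LXR falls, the 1 fall of the sphingolipid, stromal and immediate early lists and the 1 macrophage identity rise became 0, and alternative activation rises went from 2 to 1. The 14 lists still passed by camera. Changes of at least 2-fold numbered 297 with a pseudocount of 0.1, which lifts folds of low genes, and 116 with RPKM, whose values are smaller (2.77 to 3.04 TPM per RPKM) against the same pseudocount. Without the libraries numbered 2, 1732 changed (769 higher) and 94 at least 2-fold. Over fits that left out 1 library, changed genes ranged from 550 to 5010 and higher genes from 384 to 2223. Lower genes ranged from 142 to 2787 and those changed at least 2-fold from 101 to 312. The lowest of the first 2 ranges came without vehicle replicate 2 and the highest without stearic acid replicate 1. Tests of stearic acid replicate 1 are given below, and why the libraries differ was not settled. The replicate block gave 3638 changed genes (1641 higher, 1997 lower) and kept 99.0% of the calls, but the numbers gave no clear pairing: same-number deviations correlated at 0.070, 0.288 and 0.039, and 3 of 6 libraries correlated best with their own number. Median-of-ratios scaling gave 3302 (55.6% higher), RPKM 3354 (59.1%), quantile normalization 3455 (48.6%), against 51.9% higher in the reported fit. With GC and length trends removed 3946 changed, and with at least 5 TPM 2461. For lists, 0 of 14 calls held with an estimated correlation (estimates up to 0.87) and 13 passed by fry, which lost macrophage identity (0.059) and dendritic markers (0.058) and added neutrophil markers (0.011). A high estimate was not needed for a camera call to be lost. The fatty acid oxidation and PPAR list had an estimated correlation of 0.024, yet its unadjusted camera p went from 3.3e-06 to 0.015. The adjusted p of 0.29 shared by many lists covers unadjusted camera p from 0.015 for that list to 0.14 for the unfolded protein list. The LXR list passed by camera without the libraries numbered 2 (adjusted p = 0.042) and the stromal list without the filter (0.035). Of 63 named genes called, 33 passed in each of the 6 fits that left out 1 library, and 26 lost the call without the filter. None of the 934 alternative values of the 63 changed sign. For genes without overlap between groups, leaving out libraries cannot change it. Per-library weights ranged from 0.157 to 82.5 without converging and were not used. Depth of 58.1 to 80.8 M reads or read pairs (M, 1e+06) leaves 1 TPM at 19.1 to 27.7 of these units per kilobase.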

Other observations

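The gene families below and the tests of stearic acid replicate 1 and of macrophage identity were chosen after the results were seen. The GC and length correction was an unplanned setting chosen after the data were seen, with its prediction, like that of the split count, written before its result. Of 18 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs and many of which are ATF4 targets, 11 rose and 7 did not pass (median 0.45, camera adjusted p = 1.3e-06, adjusted p = 0.36 with an estimated correlation), led by Aars (log2 0.72). Of 38 genes of ribosomal RNA synthesis and the nucleolus, 22 rose (median 0.37, camera adjusted p = 7.6e-09, adjusted p = 0.36 with an estimated correlation), among them Gnl3 (log2 1.23) and Ppan (log2 1.04). Of 80 ribosomal protein genes 24 fell and 56 did not pass (median -0.21, camera adjusted p = 1.5e-09, adjusted p = 0.46 with an estimated correlation), but with RPKM or median-of-ratios scaling 1 fell (median -0.16 in each). Without vehicle replicate 2 the called synthetases and nucleolar genes numbered 0 and 1, without vehicle replicate 3 they numbered 3 and 2, without vehicle replicate 1 6 and 9 and without stearic acid replicate 3 4 and 7. Under an unadjusted limma p of 0.05 were 14 synthetases and 22 nucleolar genes without vehicle replicate 2, against 15 and 25 in the full fit. Their medians in the fit without vehicle replicate 2 were 0.45 and 0.36. The ribosomal falls numbered 2, 0 and 6 without vehicle replicates 1, 2 and 3, 12 and 0 without stearic acid replicates 2 and 3 and 37 without stearic acid replicate 1. Of 38 proteasome genes 9 rose, 28 did not pass and the immunoproteasome subunit Psmb9 fell (log2 -0.68; camera adjusted p = 0.00062, adjusted p = 0.49 with an estimated correlation). The 9 rises became 2, 0 and 0 without vehicle replicates 1, 2 and 3, 1 without stearic acid replicate 3 and 20 without stearic acid replicate 1. With no filter on low values the called synthetases, nucleolar genes and proteasome rises numbered 4, 2 and 0 and the ribosomal falls 0. Of 36 subunits of respiratory complex I, 0 passed by limma and the median was 0.01. By fry the synthetases (adjusted p = 0.054), nucleolar genes (0.058), ribosomal proteins (0.062), proteasome genes (0.15) and complex I subunits (0.99) did not pass.

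Of 12 guanylate-binding and immunity-related GTPases, 3 of which are in the interferon list, all 12 fell (median -0.85, camera adjusted p = 2.1e-08, adjusted p = 0.36 with an estimated correlation), with 6 without vehicle replicate 2 and 6 without vehicle replicate 3. Of 8 Ms4a genes, a cluster of membrane proteins that includes near copies, 7 fell (median -1.01, camera adjusted p = 8e-05, adjusted p = 0.36 with an estimated correlation), and 0 passed without vehicle replicate 2 or 3 or with no filter on low values. Under an unadjusted limma p of 0.05 were 7 without vehicle replicate 2 (median -1.07) and 7 without vehicle replicate 3 (median -0.94). Of 15 glutathione S-transferases 6 rose, 7 did not pass and Gstk1 (log2 -0.51) and Gstm4 (log2 -0.27) fell (median 0.07, camera adjusted p = 0.042, adjusted p = 0.36 with an estimated correlation). Those 2 falls became 0 without vehicle replicate 2 and 1 without vehicle replicate 1, vehicle replicate 3, stearic acid replicate 2 or stearic acid replicate 3. Of 16 V-ATPase subunits, which acidify lysosomes, 9 rose and Atp6v1g2 fell (median 0.28, camera adjusted p = 6e-06, adjusted p = 0.36 with an estimated correlation), with Atp6v0d2 highest (log2 1.67); the rises numbered 6, 4 and 3 without vehicle replicates 1, 2 and 3 and 5 without stearic acid replicate 3, and the fall became 0 without vehicle replicate 1, without vehicle replicate 3 and with no filter on low values. Of 7 matrix metalloproteinases 4 rose and 3 fell (camera adjusted p = 0.15): Mmp12 (log2 2.21), Mmp13 (log2 2.12), Mmp19 (log2 0.44) and Mmp8 (log2 0.32) rose, and Mmp2 (log2 -0.40), Mmp27 (log2 -0.40) and Mmp14 (log2 -0.38) fell. The 3 falls became 0 without any 1 vehicle library or stearic acid replicate 3 and 1 without stearic acid replicate 2. Of 10 purinergic and adenosine receptors 5 did not pass (camera adjusted p = 0.23), P2ry2 rose (log2 1.07) and P2ry12 (log2 -1.31), P2ry13 (log2 -1.18), P2rx7 (log2 -0.60) and P2ry14 (log2 -0.79) fell. The 4 falls became 2, 0 and 1 without vehicle replicates 1, 2 and 3 and 2 without stearic acid replicate 3, and the rise became 2 without stearic acid replicate 1. Of 14 C-type lectins 3 rose, Clec4n (log2 1.67), Clec4e (log2 0.69) and Clec4d (log2 0.35), 6 fell and 5 did not pass (camera adjusted p = 0.22). The lectin falls became 1 without vehicle replicate 2 and 1 without vehicle replicate 3, and the rises became 1 without vehicle replicate 3. With no filter on low values the lectins had 1 rise and 3 falls, the purinergic falls numbered 1, the metalloproteinase falls 0, and the transferase falls 1. Medians of these families kept their sign under RPKM, median-of-ratios and quantile scaling. By fry the GTPases (adjusted p = 0.019), Ms4a genes (0.047), transferases (0.0028), V-ATPase subunits (0.0075) and metalloproteinases (0.0028) passed. The purinergic receptors (fry adjusted p = 0.15) and lectins (0.15) did not. As fry tests members alone and 24.7% of all tested genes changed, a pass by fry need not set a family apart from other genes.

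The count of 2856 changed genes was set against the other splits of the 6 libraries into 3 and 3. Of 10 splits, 1 reached it, the real one, and the highest other gave 0 by limma; the real split had 4671 genes under an unadjusted p of 0.05 and the others 16 to 2250, the last with stearic acid replicate 1 grouped with vehicle replicates 1 and 3. With 10 splits no share under 0.05 can arise. GC content and length differed between libraries: deviations from the group mean correlated across genes with length at -0.36 in vehicle replicate 2 and 0.44 in vehicle replicate 3, and with GC content at 0.58 in vehicle replicate 1 and -0.35 in vehicle replicate 2. Deviations within a group do not bear on differences between the groups. Across genes the log2 fold change correlated with GC content at 0.15 and with length at -0.08 (Spearman). After each library's trend was removed, 93.2% of the 2792 called genes with a known length stayed called with the same sign, which argues against these trends as the main source of the count. Vehicle replicate 2 had Lars2 at 381 TPM against 143 to 155 TPM in the other vehicle libraries. Stearic acid replicates 1 to 3 had Lars2 lower than any vehicle library, at 83.3, 101 and 74.1 TPM. Rn7s1 ranged from 2.98 TPM in vehicle replicate 3 to 93.7 TPM in stearic acid replicate 2. In these libraries Rn7s2 was at 75.1 and 97.4 TPM, so the low value of Rn7s1 was not shared by Rn7s2.

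Stearic acid replicate 1 moved less than the others, with slopes on the mean change of 0.69, 1.33 and 0.98 in replicates 1 to 3. Lower depth would weigh least on abundant transcripts, yet in 532 called genes with a mean of at least 100 TPM its log2 changes were a median of 0.503 of those in replicate 2 (95% bootstrap interval over genes 0.480 to 0.524). Dilution by vehicle-like RNA or unexposed cells would give all genes 1 share of the replicate 2 change on the TPM scale, and called PPAR list members exceeded the other called genes by 0.243 in median share (95% interval 0.101 to 0.688, over genes that are not independent). As that list was picked after the results were seen, the interval cannot decide on dilution. Medians were 0.73 for that list and 0.80 for the lysosome. They ran from 0.25 for glycolysis to 1.01 for LXR targets over the lists compared, though risers (0.49) and fallers (0.49) as wholes were alike. What made the response of replicate 1 smaller was not settled.

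The fall of macrophage identity genes could reflect fewer macrophages and more of another cell type. The members' log2 folds had a standard deviation of 0.398 against a median SE of 0.115, and Cd68 rose. That rise did not pass without any 1 vehicle library or stearic acid replicate 3. A plain loss of macrophages would lower all members alike only if no other cells present expressed them, which was not tested. The folds were thus not uniform, but this cannot decide whether such a loss took part. Among neutrophil and dendritic markers, 2 of 3 and 0 of 5 tested rose, with the neutrophil gene S100a8 at 6.41 TPM. The lymphoid, stromal and erythroid lists had 1, 2 and 0 tested members, too few for a count of risers to tell. With no filter on low values they had 7, 11 and 8 tested members and 0, 0 and 1 called risers, the last a gene below the filter. The neutrophil and dendritic lists then had 13 and 14 tested members and 0 risers each. The highest means with stearic acid among lymphoid and stromal markers past the filter were 1.27 TPM (Cd79b) and 1.34 TPM (Acta2). The other members of both lists, and all 12 erythroid and mast cell markers, averaged under 1 TPM over the 6 libraries. Levels this low argue against a large share of cells carrying these lymphoid, stromal, erythroid or mast cell markers. What lowered the macrophage identity genes was not settled.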
